A study of Mus musculus with 4 samples.

How the data were processed

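The samples were subcutaneous tumours grown from B16-F10-luc-G5 cells, a luciferase-carrying line of the mouse B16 melanoma, in the abdominal area of mice. Per the labels, tumours were dissected on day 10 from 2 wild-type mice and 2 mice lacking VAP-1, vascular adhesion protein 1, the amine oxidase encoded by Aoc3. Total RNA was extracted with a Qiagen kit, per the labels' protocols, and 100 ng was amplified and biotin labelled with the Illumina TotalPrep kit with 14 h of in vitro transcription. One array was hybridised per tumour. The array model, the scanner software and the way beads were summarised are not given in the sources used here, nor are slide positions or scan dates, so no batch was available to test.

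The deposited unnormalized table holds a bead-summarised probe intensity per array, on a linear scale, with no detection p-value and no control probes marked. Its medians differed between arrays, and its lowest values lay near 30, so it was neither normalized nor background subtracted. The authors' processed table also holds intensity. Each of its columns equals the rank-wise mean of the sorted columns of the unnormalized table, which is quantile normalization on the linear scale. The unnormalized table has 46643 rows with numeric identifiers that name no gene, and the processed table has 46632 rows with Illumina probe identifiers. Rows were paired through their 4 values: the unnormalized table was quantile normalized and each processed row was matched to the nearest row within 0.001 on the log2 scale. All 46632 processed rows found a single partner. The largest distance was 0.000335 and the smallest distance to any next nearest row was 0.00217. With the wild-type columns exchanged only 147 rows matched, with the knockout columns exchanged 140, and with the groups exchanged 0. The 11 unnormalized rows without a partner were left out. Gene symbols came from the platform annotation for the processed table's probes: 29976 probes had 1 symbol, 10 had several and 16646 had none. Gene identifiers of 29921 probes were found in the RefSeq gene table, which changed 0 symbols, and 17711 distinct genes were named. Probes with several symbols were given no gene name.

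Values were analysed with limma 3.58.1 in R 4.3.3, and the pairing of rows used Python 3.11.15, numpy 2.4.6, scipy 1.17.1 and pandas 2.3.3. The test was planned for a table with or without detection p-values, and the form for a table without them was used. Background was corrected with normexp at an offset of 50, values were quantile normalized between the 4 arrays and log2 was taken. Probes with a normalized mean above the 40th percentile of all probes were kept, which left 27979 probes, of which 19761 carried a single gene symbol, for 13231 genes. The filter level was 6.07 on the log2 scale, and normalized values ran from 5.65 to 14.72, so probes close to the filter level lie near the floor and their differences are compressed. The background correction and the offset also shrink differences of dim probes. Differences are knockout minus wild type on the log2 scale with the standard error (SE) of the moderated fit.

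The comparison used lmFit and eBayes, two-sided, with Benjamini-Hochberg adjustment over the 27979 probes and a threshold of 0.05. The fit has 2 residual degrees of freedom and a prior of 2.49. An exact permutation test of 2 arrays against 2 cannot go below 0.333, so no per-gene exact test was run. Labels state 2 mice per genotype, so replicates are separate tumours, and 4 arrays limit the precision of every value.

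The steps were tested on simulated data: in 20 simulations of 27979 probes with 200 changed, variances were drawn from the fitted prior. At the adjusted threshold the test recovered 1.65% of 2-fold and 74.6% of 4-fold changes, with a mean of 3.15 false calls among 79.45. That recovery holds for the simulated share of changed probes, while in the data an estimated 76.6% of probes were unchanged. At an unadjusted p under 0.05 the test recovered 94.6% of 2-fold changes, and 5% of unchanged probes passed. With limma camera at an unadjusted p under 0.05, a simulated list of 25 genes shifted by 0.5 passed in 20 of 20 simulations. An unshifted list passed in 1 of 20. The real lists had to pass after adjustment over 25 lists, a stricter rule. The simulated probes were drawn independently of each other. Keratinocyte and skeletal muscle genes had estimated correlations of 0.605 and 0.589 in the data, so these list rates do not carry over to such lists.

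Groups, tests, alternatives, the rule for named genes and 25 gene lists were fixed before the data were examined. The named genes are Aoc3 and 10 per direction. Those were to be the largest changes past the threshold with a single gene symbol and groups that do not overlap. Where fewer pass, places go to the genes of smallest unadjusted p whose groups do not overlap and whose means differ by at least 1.5-fold, and all 20 places were filled so. Of each list, up to 4 members of smallest p may be named, and every member of a list with fewer than 10 measured genes. Of the 696 list members, 623 matched a gene of the probe annotation and 542 were kept. Each gene was represented by its brightest probe in the list tests, and by the probe of smallest p among the named genes.

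The lists covered melanocyte and melanoma genes, endothelium, pericytes and smooth muscle, fibroblasts and matrix, granulocytic myeloid cells, monocytes with macrophages and dendritic cells, T and NK cells, B and plasma cells, leukocyte adhesion, hypoxia, angiogenic signalling, chemokines and cytokines, interferon response, antigen presentation, proliferation, adipocytes, skeletal muscle, skin keratinocytes, erythroid cells, amine oxidases, redox response, immediate early and handling genes, ribosomal proteins, sex-linked genes, and complement with coagulation. Lists with at least 5 measured genes were tested with limma camera at a preset inter-gene correlation of 0.01, two-sided, with adjustment over the 25 lists. Estimated correlations and limma fry were alternatives. Camera asks whether the genes of a list differ more than the other genes do, and fry whether they differ between the groups at all. A list can therefore pass 1 of these tests and not the other. With estimated correlations camera gave each of the 25 lists an adjusted p of 0.986 or 0.993, so that setting separates no list from the others. It rests on the 2 residual degrees of freedom, so a call can be lost there at any correlation. For erythroid genes the camera p rose from 0.00513 to 0.0976 although the estimated correlation was below the preset one.

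Alternatives changed the scaling between arrays, the background correction, the source of the values, the filter, the moderation, the threshold, the array weights, the arrays used, and the set test. A filter at the 70th percentile was added after the data were seen, in place of one on detection p-values, which the table used here does not carry. The 3 further gene lists given among the other observations were chosen after the values had been seen. Gene order along the chromosome came from the RefSeq table, and no coordinates are given because the genome build of the probes is not given in the sources used here.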

Results

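Gene expression was measured with Illumina bead arrays in B16-F10-luc-G5 melanoma tumours taken 10 days after injection into 2 wild-type mice (replicates 2 and 3) and 2 VAP-1 knockout mice (replicates 1 and 2). VAP-1 is a cell surface amine oxidase of endothelium, smooth muscle and fat that takes part in leukocyte traffic. The injected cells were the same in both groups, so the comparison asks how tumours differ when the host lacks VAP-1. Median unnormalized signal was 63.34 and 55.31 in wild-type replicates 2 and 3 and 64.81 and 68.27 in knockout replicates 1 and 2. The 75th percentile was 96.99 and 88.28 against 112.86 and 126.75. After normalization the knockout arrays resembled each other most, with an SD of 0.244 for the log2 difference over probes, against 0.392 between the wild-type arrays. Each wild-type array lay as far from knockout replicate 2 (0.396 and 0.392) as from the other wild-type array, and farther from knockout replicate 1 (0.449 and 0.474).

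Aoc3, the gene that encodes VAP-1, had a log2 signal of 7.98 and 7.16 on the wild-type arrays and of 7.27 and 7.14 on the knockout arrays. The difference of -0.37 ± 0.29 (SE, n = 2 each, 95% interval -1.15 to 0.41) was within the spread between replicates, with limma adjusted p = 0.606. Wild-type replicate 3 lay at the level of the knockout arrays, and without wild-type replicate 2 the difference was 0.04. Under median scaling it was 0.02. A second Aoc3 probe near the floor differed by -0.05 ± 0.12. Where these probes lie relative to the deleted part of the gene is not given in the sources used here. The injected cells, the same in both groups, may also add Aoc3 signal of their own. The Aoc3 signal therefore does not check the genotypes, and groups are named as the arrays are labelled. Among 11 measured amine oxidase genes the median difference was 0.09 (camera adjusted p = 0.737). Aoc2, the neighbouring copper amine oxidase gene, was higher in the knockout by 1.03 ± 0.14 and was the 1 member past 0.05 adjusted over the list alone, with 0 over all probes. Kdm1a (-0.41 ± 0.22), Maob (0.17 ± 0.10) and Loxl2 (-0.17 ± 0.12) did not pass, and Loxl2 was higher in the knockout after both other scalings (0.26 and 0.03). Kdm1a, with 9.65 and 10.23 on the wild-type arrays, differed by -0.7 without wild-type replicate 2 and by -0.08 under median scaling.

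The widest gaps between the groups among the genes named by rule were at Erdr1, higher in the knockout, and at a beta-globin gene and the neutrophil and monocyte gene S100a8, lower in the knockout. Erdr1, a gene of the pseudoautosomal region of the sex chromosomes, was 6.19-fold higher in the knockout, at 13.36 ± 0.08 against 10.73 ± 0.25 (log2 signal, mean ± SD, n = 2 each), and its second probe differed by 2.65 ± 0.17 (SE). S100a8, which encodes a subunit of the calcium-binding protein calprotectin, was 9.62-fold lower in the knockout, at 7.39 ± 0.46 against 10.66 ± 0.50. A probe for the adult beta-globin gene Hbb-bs was 9.68-fold lower, at 7.73 ± 0.49 against 11.01 ± 0.17. The 4 other Hbb-bs probes, all brighter and nearer the top of the scale, differed by -1.68 to -1.08. None of these passed the threshold: each of the 20 genes named by rule had a limma adjusted p of 0.102.

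Among the 10 genes named as higher, the RNA-binding protein gene Hnrnph1 was higher by 1.84 ± 0.13 (SE), with all 4 of its probes higher. Clk2, a kinase of splicing factors, was higher by 1.80 ± 0.13, and the splicing regulators Rbm5 and Hnrnpdl by 1.38 ± 0.10 and 1.46 ± 0.11. A second probe, near the floor, differed less for Clk2 (0.32 ± 0.14), Rbm5 (0.13 ± 0.10) and Hnrnpdl (0.09 ± 0.13). Chkb, which encodes a choline kinase of phosphatidylcholine synthesis, was higher by 1.36 ± 0.10, with 3 probes between 1.22 and 1.40. The remaining genes were Map11 (1.88 ± 0.13), Ivns1abp (1.74 ± 0.12, and 0.92 ± 0.14 at a second probe), Gpr137b, a lysosomal membrane protein gene (1.62 ± 0.11), and Rgl2, an exchange factor for Ral GTPases (1.58 ± 0.10).

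Of the 10 genes named as lower, Hbb-bs and Hbb-bt encode adult beta-globin, and the Hbb-bt probe of smallest p differed by -1.74 ± 0.12. Cck, which encodes the peptide hormone cholecystokinin, differed by -1.20 ± 0.10, and Ebp, an enzyme gene of cholesterol synthesis, by -1.19 ± 0.13. Slirp, a stabiliser of mitochondrial transcripts, differed by -1.05 ± 0.11 and at a second, brighter probe by -0.28 ± 0.14, the nucleolar protein gene Nifk by -1.03 ± 0.10, and Gcat, a mitochondrial enzyme gene of threonine breakdown, by -0.99 ± 0.10. Gcat's second probe, near the floor, differed by 0.03 ± 0.11. The uridylyltransferase gene Tut7 (-1.53 ± 0.12) and Zfand6 (-1.35 ± 0.12) had other probes that went the opposite way, by 0.68, 0.44 and 0.21 for Tut7 and by 0.20 for Zfand6.

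**Figure D1:**
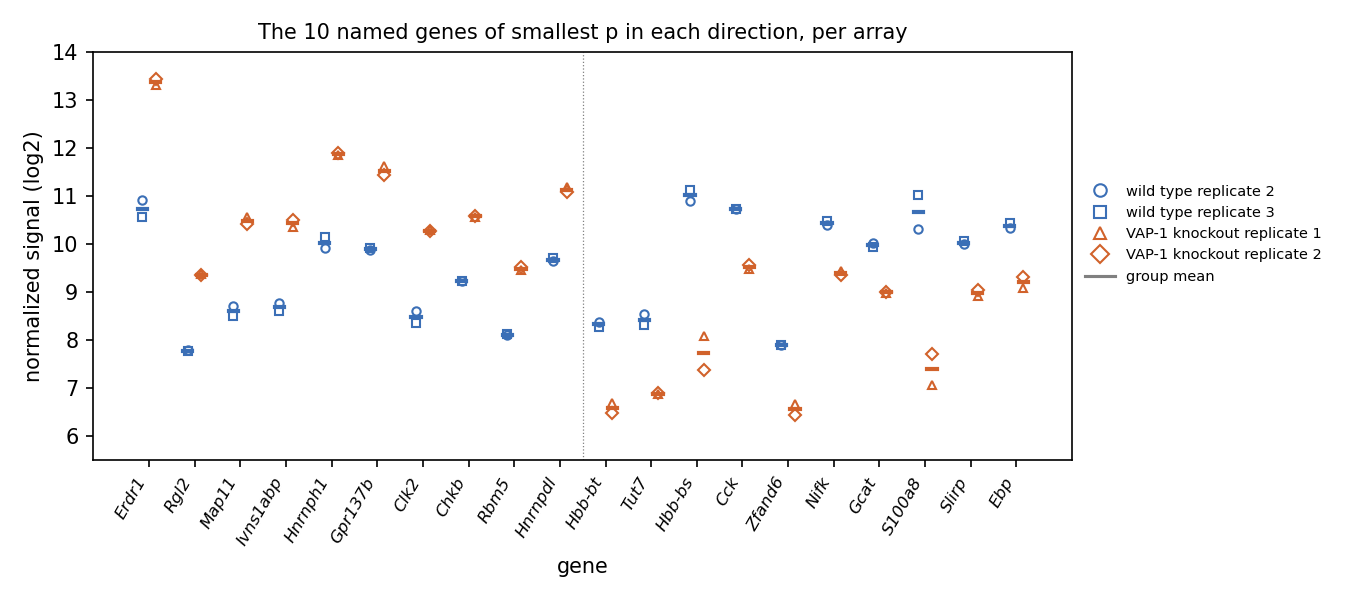
Normalized log2 signal (vertical axis) of the 20 genes named by rule (horizontal axis), 10 higher and 10 lower in the knockout, with 1 point per array and a short bar for each group mean. The groups do not overlap for any of them, with the widest gaps for Erdr1 (2.63), S100a8 (-3.27) and the Hbb-bs probe shown (-3.28). The other Hbb-bs probes differed less.

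Across 27979 probes limma called 0 at an adjusted p under 0.05, and the smallest adjusted p was 0.102, shared by 148 probes. At an unadjusted p under 0.05 there were 4582 probes (16.4%), 2590 higher and 1992 lower in the knockout, where 5% would pass among unchanged probes. With at least 1.5-fold added, 1268 probes of 850 named genes were higher and 879 probes of 673 named genes lower. At 2-fold without overlap of the groups there were 413 higher and 146 lower. Groups did not overlap for 49.2% of probes, where the average over the 3 splits of the 4 arrays into 2 and 2 is 33.3%. Probes of an array vary together, so with 3 splits neither this share nor the 16.4% can be tested against chance. Other moderation called few probes, 4 with an intensity trend and robust prior and 1 with none. Leaving out wild-type replicate 2 or 3, which bases the spread on the closer knockout pair, called 1801 and 889, and leaving out either knockout array called 0. The share of higher probes among those with at least 1.5-fold and an unadjusted p under 0.05 was 59.1%, and it was 98.7% under median scaling and 82% when arrays were scaled by the 75th percentile, which shifted the median of all kept probes to -0.144 from -0.021.

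Genes of neutrophils and related granulocytic myeloid cells were lower in the knockout at the top of their list. Beta-globin probes were lower on the same arrays (median -1.6), and whether less blood in these tumours also lowered the granulocytic genes was not tested. S100a9, the partner of S100a8, was 5.20-fold lower, at 6.81 ± 0.36 against 9.18 ± 0.69 (log2 signal, mean ± SD, n = 2 each). Fpr2, a formyl peptide receptor gene, differed by -0.61 ± 0.12 (SE), and Mmp9, which encodes gelatinase B, by -0.73 ± 0.16. Of 15 measured members, 5 fell adjusted over the list alone, 0 over all probes, and the fifth, named after its values were seen, was the antimicrobial peptide gene Camp (-0.56 ± 0.14). The other 10 did not pass, many of them close to the floor, and 4 of them had higher means in the knockout, among them Ly6c1 (0.21 ± 0.23) and Lcn2 (0.11 ± 0.36), which were as bright as Fpr2 and Camp. The list passed with limma fry (adjusted p = 0.0172) but not with camera (median -0.08, mean -0.51, adjusted p = 0.0773). It did not pass camera with an estimated correlation either, where no list passed (adjusted p = 0.986), at an estimate of -0.0612, below the preset 0.01. It passed camera with median scaling (adjusted p = 0.00232), 75th percentile scaling (0.00606) and the filter at the 70th percentile (0.0228), a filter chosen after the data were seen. It also passed without wild-type replicate 3 (0.0388) and without knockout replicate 1 (0.0195), the array with more skin and muscle signal. It did not pass without wild-type replicate 2 (0.192) or knockout replicate 2 (0.164), and the range over all alternatives was 0.00232 to 0.986.

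Of 38 measured chemokine and cytokine genes, 3 fell and 1 rose adjusted over the list alone, 0 over all probes, and the list had a median of -0.08 (camera adjusted p = 0.173). The genes that fell encode Ccl4 (-1.39 ± 0.15), Ccl12 (-0.97 ± 0.18) and Ccl7 (-0.63 ± 0.12), which attract monocytes and other leukocytes. Ccl21a, a chemokine of lymphatic vessels and lymphoid tissue, rose by 1.38 ± 0.23. Under median scaling this list passed (adjusted p = 0.0404, range over alternatives 0.0404 to 0.986). Among 30 genes of monocytes, macrophages and dendritic cells (median -0.07, adjusted p = 0.906), 0 passed. The endotoxin co-receptor gene Cd14 (-0.80 ± 0.14) and Cd80 (-0.62 ± 0.22, from -0.89 to -0.18 over the alternatives) were lower. Retnla, a marker of alternatively activated macrophages (1.06 ± 0.23), and Siglec1 (0.30 ± 0.10) were higher. Leukocyte adhesion genes (27 measured, median -0.13, adjusted p = 0.222) had 0 members past the threshold, with Icam2 at -0.40 ± 0.11, Cd99l2 at -0.52 ± 0.15 and Vcam1 at -0.51 ± 0.16. The 3 other kept Vcam1 probes did not go the same way, the 2 other Cd99l2 probes differed by -0.46 and 0.08, and Itgav (-0.35 ± 0.14) was level under median scaling (0.01), with 1 of its other probes at 0.05.

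T and NK cell genes (18 measured, median 0.04, adjusted p = 0.872) and B and plasma cell genes (9 measured, median -0.04, adjusted p = 0.989) had 0 members past the threshold, and most lay near the floor. Il2rb differed by -0.35 ± 0.11, Klrd1 by 0.31 ± 0.11 and H2-Ob by -0.37 ± 0.13. Among 22 antigen presentation genes (median 0.14, adjusted p = 0.468) the class I gene H2-D1 (0.65 ± 0.15) and its transactivator Nlrc5 (0.80 ± 0.21) were higher. The immunoproteasome gene Psmb10 (-0.57 ± 0.11) and Psme1 (-0.43 ± 0.12) were lower, and 0 passed. Of 29 interferon response genes (median 0, adjusted p = 0.906), Oas2 (0.67 ± 0.11), Stat2 (0.51 ± 0.10) and Eif2ak2 (0.64 ± 0.13) rose and Rsad2 (-0.50 ± 0.10) fell adjusted over the list alone, 0 over all probes. Complement and coagulation genes (11 measured, median 0.12, adjusted p = 0.656) had 0 past the threshold, with Cfp at 0.33 ± 0.16.

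Beta-globin, alpha-globin and Alas2 transcripts were lower in the knockout tumours. All 10 probes of the adult beta-globin genes Hbb-bs and Hbb-bt were lower on both knockout arrays, with differences from -3.28 to -1.08 and a median of -1.60 (3.02-fold), and the median was -1.58 and -1.80 under the other scalings. These genes are nearly identical, so their probes cannot separate them. Most of the 10 probes lay near the highest normalized value of 14.72 in wild type, where differences may be compressed, so the size of the fall is uncertain. Hba-a1, an alpha-globin gene with a near-identical copy, differed by -1.07 ± 0.24, and Alas2, the erythroid enzyme gene of haem synthesis, by -1.52 ± 0.50. The Alas2 difference was -2.22 without knockout replicate 1 and -0.83 without knockout replicate 2. Of 13 measured erythroid genes, 1 (Hbb-bs) fell adjusted over the list alone, and 0 over all probes. Apart from Hbb-bs, Hbb-bt, Hba-a1 and Alas2, the members differed by -0.28 (Hbb-b2) to 0.09 (Fech), and most of these lay near the floor. The list passed with camera (median -0.16, mean -0.50, adjusted p = 0.0428), and the call was lost with fry (adjusted p = 0.241). The estimated correlation was -0.0727, below the preset 0.01. With it the call was lost as well (camera adjusted p = 0.986), through the 2 degrees of freedom of that setting and not through correlation. It was also lost without wild-type replicate 2 (adjusted p = 0.202), with a median of -0.18, and the range over all alternatives was 0.000139 to 0.986. Without knockout replicate 1, the array with more skin and muscle signal, the list passed (adjusted p = 0.00731).

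Vessel genes went both ways. Among 28 endothelial genes (median -0.14, camera adjusted p = 0.468) the tight junction gene Cldn5 (-0.68 ± 0.15) and the VEGF receptor gene Kdr (-0.55 ± 0.14) were lower. Vwf, which encodes von Willebrand factor, was higher (1.60 ± 0.41), with 10.06 and 8.88 on the wild-type arrays against 11.07 and 11.06, and so was Lyve1 of lymphatic endothelium (0.42 ± 0.11). None passed adjusted over the list alone, the list median was 0.15 under median scaling, and without wild-type replicate 3 the list passed (median -0.25, adjusted p = 0.0388). Without wild-type replicate 2 it did not (median 0, adjusted p = 0.799), and the range over alternatives was 0.0388 to 0.986. Of 28 angiogenic signalling genes (median -0.13, adjusted p = 0.748), Vegfb (0.97 ± 0.11) and Fgf1 (0.56 ± 0.12) rose adjusted over the list alone. The angiogenesis inhibitor gene Thbs2 (-0.84 ± 0.12) and the Tie2 ligand gene Angpt2 (-0.65 ± 0.13) fell, as did Cxcr4 (-0.79), named after its values were seen, with 0 over all probes. The second Angpt2 probe, near the floor, differed by 0.03 ± 0.10. Of 15 pericyte and smooth muscle genes (median -0.03, mean -0.18, adjusted p = 0.509), the pericyte proteoglycan gene Cspg4 (-0.56 ± 0.10) and the smooth muscle actin genes Actg2 (-0.81 ± 0.14) and Acta2 (-0.73 ± 0.17) fell adjusted over the list alone, 0 over all probes. The 2 other Acta2 probes differed by 0.15 ± 0.20 and -0.26 ± 0.13. The smooth muscle gene Smtn was higher (0.65 ± 0.17) and did not pass, and its 2 other probes, near the floor, differed by -0.05 and -0.04. Fibroblast and matrix genes (28 measured, median 0.11, adjusted p = 0.737) had 0 past the threshold. The protease gene Mmp3 differed by -1.14 ± 0.20, Sparc by -0.61 ± 0.17 and the fibronectin gene Fn1 by 0.50 ± 0.16.

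**Figure D2:**
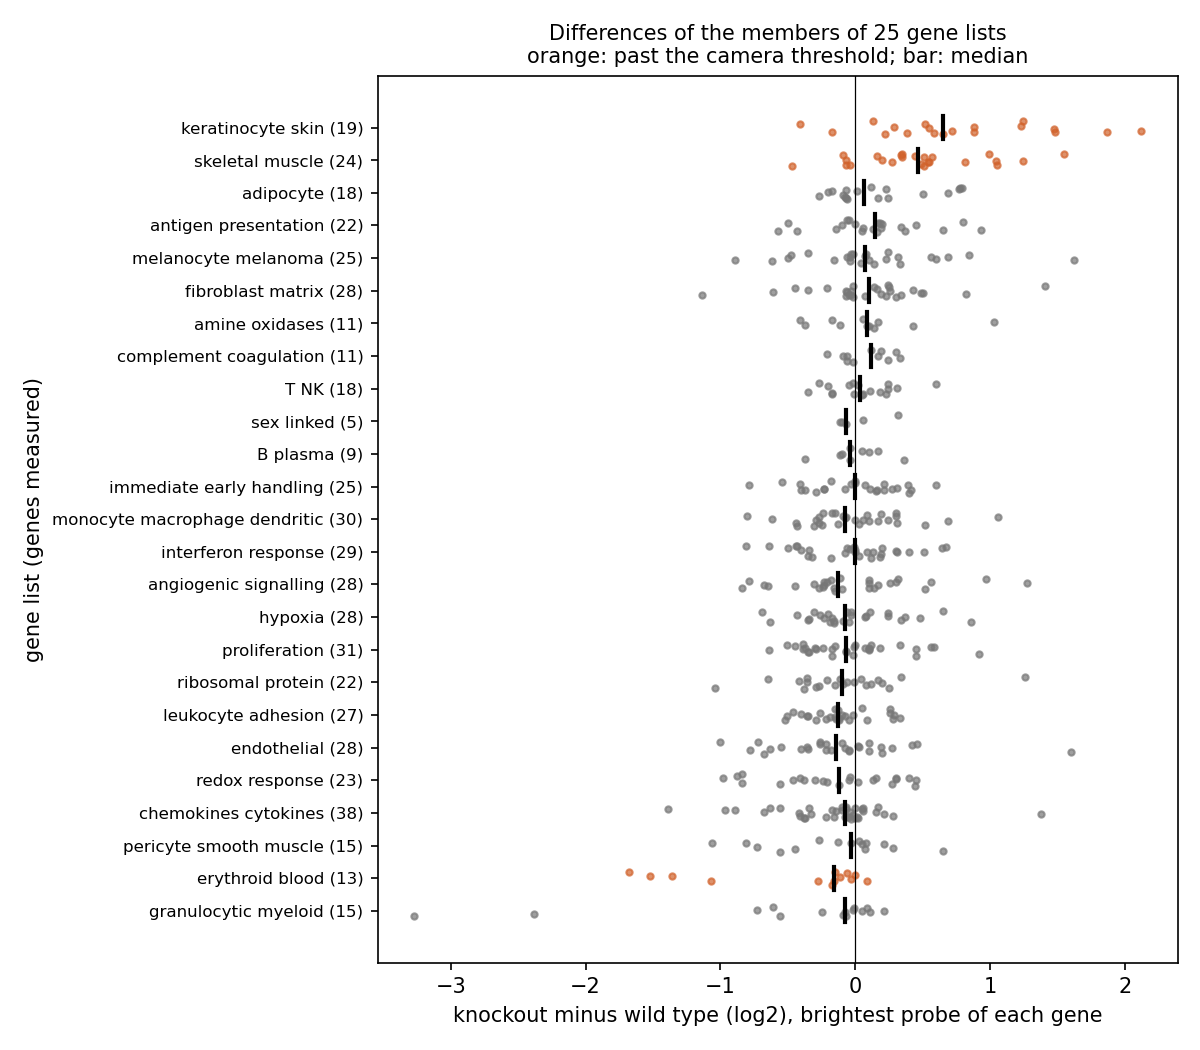
Difference between knockout and wild type (log2, horizontal axis) of the brightest probe of each measured gene in the 25 lists fixed beforehand (vertical axis, genes measured in parentheses), with 1 point per gene, a bar at the list median and orange for lists past the camera threshold. Keratinocyte (median 0.65) and skeletal muscle genes (median 0.47) lie mostly above 0, and a few erythroid and granulocytic genes lie far below it.

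Of 25 melanocyte and melanoma genes (median 0.07, adjusted p = 0.468), Gpr137b (1.62 ± 0.11) and the transcription factor gene Tbx2 (0.60 ± 0.11) rose adjusted over the list alone, 0 over all probes. The melanocyte transcription factor gene Sox10 was higher (0.84 ± 0.20) and the pigment gene Oca2 lower (-0.62 ± 0.14). Proliferation genes (31 measured, median -0.07, adjusted p = 0.748) had 0 past the threshold, with the centromere genes Cenpe at 0.92 ± 0.18 and Cenpa at 0.45 ± 0.10, and the replication gene Mcm6 at -0.64 ± 0.13. Of 28 hypoxia genes (median -0.07, adjusted p = 0.748), 1 fell adjusted over the list alone, the oxygen sensor gene Egln3 (-0.69 ± 0.10), and Vegfa (0.65 ± 0.17) did not pass. Of 23 redox genes (median -0.12, adjusted p = 0.468), 4 fell adjusted over the list alone, 0 over all probes. These were the glutathione transferase gene Gsta4 (-0.84 ± 0.13), the superoxide dismutase gene Sod1 (-0.46 ± 0.10) and the peroxiredoxin genes Prdx2 (-0.88 ± 0.19) and Prdx4 (-0.84 ± 0.19). Sod1's second probe did not go the same way.

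Genes of skin and skeletal muscle, tissues that lie next to a subcutaneous tumour, were higher in the knockout, mainly on the array of knockout replicate 1. The 19 keratinocyte genes had a median difference of 0.65, with camera adjusted p = 0.0189. With an estimated correlation (0.605 between these genes), where no list passed, their call was lost (camera adjusted p = 0.986). Their median above the wild-type mean was 1.24 in knockout replicate 1 and 0.11 in replicate 2. Lor, which encodes the cornified envelope protein loricrin, had 11.87 and 9.65 on the knockout arrays against 9.13 and 8.15. Ivl, for involucrin (1.48 ± 0.43), and the keratin gene Krt1 (0.88 ± 0.28) were higher, and Dsg3 lower (-0.41 ± 0.17), though level under median scaling (0.01) and at 0.11 on its second probe. The 24 skeletal muscle genes had a median difference of 0.47, with adjusted p = 0.00312, also lost with an estimated correlation (0.589, adjusted p = 0.986). Their median was 0.67 in knockout replicate 1 and 0.19 in replicate 2. Atp2a1, the calcium pump gene of fast muscle, differed by 1.55 ± 0.44 and Ckm, muscle creatine kinase, by 0.55 ± 0.18. No member of either list passed adjusted over the list alone. With fry both lists had an adjusted p of 0.762. Without knockout replicate 1 both calls ended with smaller medians, 0.11 for keratinocyte and 0.18 for muscle genes (adjusted p = 0.351 and 0.123). Without wild-type replicate 2 they also ended, but with medians of 0.61 and 0.46 (adjusted p = 0.142 and 0.104), close to the main ones. Over all alternatives the adjusted p ranged from 5.6e-11 to 0.986 for keratinocyte and from 6.24e-10 to 0.986 for muscle genes. Adipocyte genes (18 measured, median 0.06, adjusted p = 0.560) had 0 past the threshold, and Lpl had 10.61 in knockout replicate 1 against 9.43 in replicate 2, with a difference of -0.09 at its second probe.

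**Figure D3:**
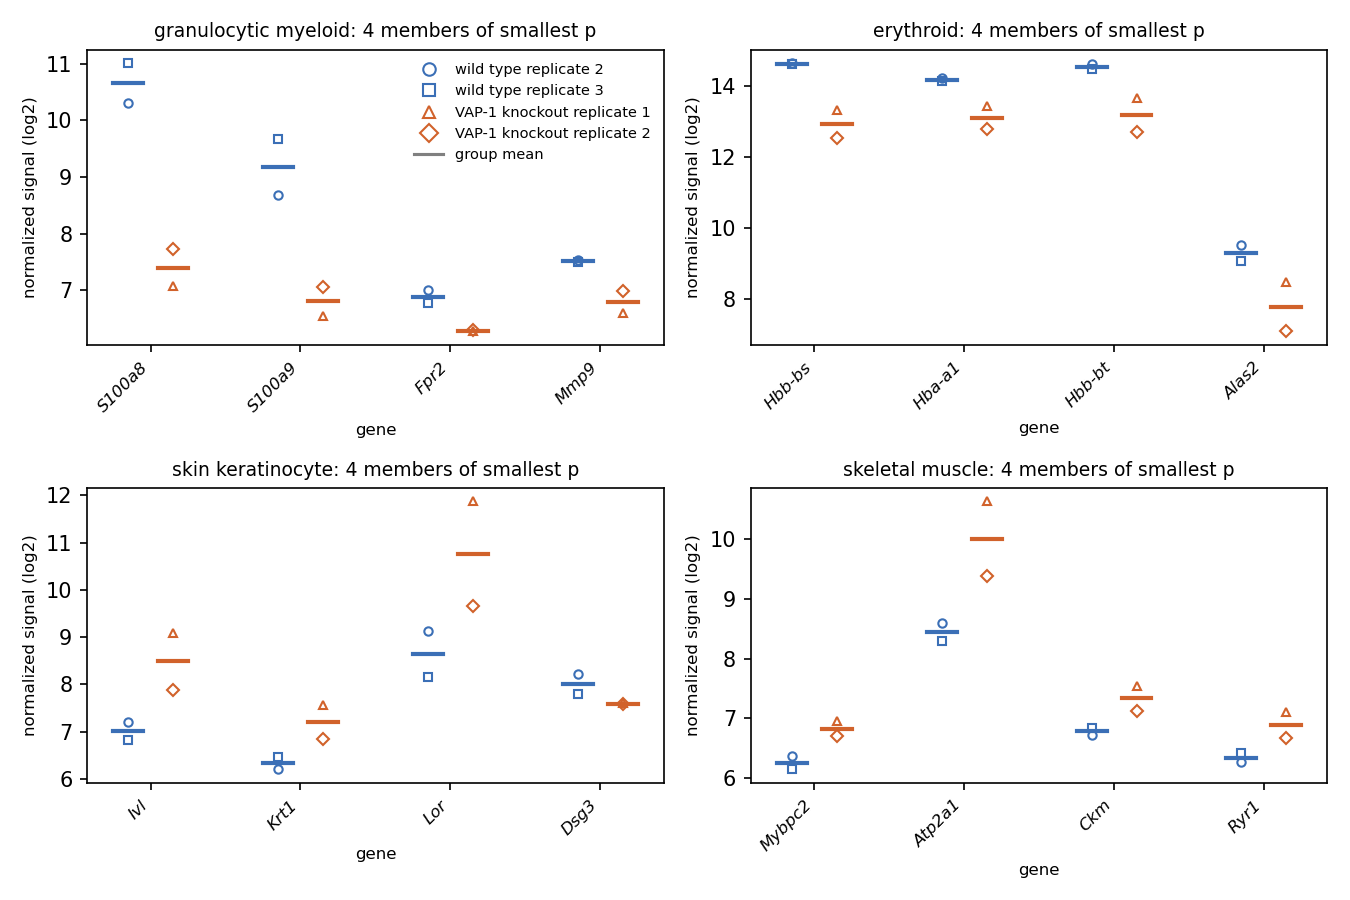
Normalized log2 signal (vertical axes) on each of the 4 arrays for the 4 members of smallest p (horizontal axes) of the granulocytic myeloid, erythroid, keratinocyte and skeletal muscle lists, with 1 point per array and a short bar for each group mean. S100a8 lies at 10.31 and 11.01 in wild type against 7.07 and 7.72 in the knockout, while Lor and Atp2a1 stand highest in knockout replicate 1 (11.87 and 10.62).

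Immediate early and handling genes (25 measured, median 0, camera adjusted p = 0.989) had 0 past the threshold, with Ccn2 at -0.79 ± 0.23. Of 22 ribosomal protein genes (median -0.10, adjusted p = 0.737), Rps24 rose by 1.26 ± 0.20 adjusted over the list alone, 0 over all probes, and its 2 other kept probes did not go the same way. Rplp0 differed by -1.04 ± 0.25, and under median scaling the list passed (adjusted p = 0.0251, range over alternatives 0.0251 to 0.986). Sex-linked genes (5 measured, median -0.07, adjusted p = 0.954) lay near the floor on all arrays, with 6.64, 6.69, 6.57 and 6.55 for Xist and 6.25, 6.36, 6.63 and 6.62 for Eif2s3y in the order wild type 2 and 3, knockout 1 and 2. Of the 14 lists with a median below 0, 9 had a median above 0 under median scaling and 0 under 75th percentile scaling, over the same probes. Of the 9 above 0, 0 and 3 had a median below 0 under these scalings.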

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

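The filter at the 70th percentile was chosen after the data were seen and the other settings before. Counts past the adjusted threshold were 0 with every scaling, background correction, value source, filter and array weighting tried, and at an adjusted p under 0.10. They were 4 (3 higher, 1 lower) with an intensity trend and robust prior and 1 (1 higher, 0 lower) without moderation. With an unadjusted p and 1.5-fold they were 2147 (1268 higher, 879 lower), and with 2-fold and no overlap 559 (413 higher, 146 lower). Leaving out an array gave 0 to 1801 probes, 0 to 954 higher and 0 to 847 lower, because without a wild-type array the spread rests on the closer knockout pair. Probes with an unadjusted p under 0.05 and 1.5-fold numbered 972 without moderation (657 higher, 315 lower), 3002 higher and 40 lower under median scaling, and 349 lower under 75th percentile scaling. Leaving out an array gave 1368 to 3652, with 430 to 1789 lower. Gene lists past the threshold numbered 3 in the main setting, 6 under median scaling, 1 with fry, 0 with an estimated correlation and 0 to 5 when an array was left out.

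Changing the filter, the moderation or the array weights left each difference as it was, so those settings could not reverse one. No probe passed the threshold in the main setting, so keeping its side meant not passing. Of 1560 values for 120 probes of named genes under the alternatives, 1475 kept their direction and their side of the threshold. A further 74 kept their direction and passed the threshold, 71 of them without a wild-type array, and 11 reversed. The Aoc3 difference reversed to 0.02 under median scaling and ranged from -0.78 to 0.04 when an array was left out. Its second probe then ranged from -0.15 to 0.04. Also reversed under median scaling were Pnpla2 (0.06), Loxl2 (0.26), Dsg3 (0.01), Itgav (0.01), Uty (0.04) and Xist (0.05). Under 75th percentile scaling Loxl2 (0.03) and Fcrla (-0.05) reversed. In the main setting these differences lay between -0.41 (Dsg3) and 0.17 (Fcrla). Only the scaling between arrays was changed in these settings, so these reversals follow from it. No paired analysis was possible because the groups share only replicate number 2. Detection on all 4 arrays and slide as a block were not run, since neither detection p-values nor slides were among the data used here, and normexp without negative controls equals the main setting. Signal close to background limits what dim probes can show.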

Other observations

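The 3 gene lists described first, their tests, the test of the shared shift for Aoc2, the interval around the median of its neighbours and the bright-probe comparison were chosen after the results had been seen.

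Nuclear-encoded mitochondrial genes mostly had lower means in the knockout, but neither list passed once correlation between genes was estimated. Of 69 genes for subunits of the respiratory chain and ATP synthase, 63 were lower, with a median difference of -0.44, and 6 fell adjusted over the list alone. Cox7a2 (-1.08 ± 0.14, SE) and the complex I gene Ndufa7 (-1.07 ± 0.14) are examples. Of 71 mitochondrial ribosome genes, 65 were lower (median -0.35) and 8 fell adjusted over the list alone, such as Mrps16 (-1.01 ± 0.17) and Mrpl20 (-1.15 ± 0.15, with a second probe at 0.13). Limma camera gave p = 1.41e-09 and 6.63e-11, but with an estimated correlation p = 0.281 and p = 0.306, at estimated correlations of 0.411 and 0.545 between genes. Fry gave an adjusted p of 0.15 for both. Wild-type replicate 2 lay below replicate 3 by a median of -0.27 and -0.40. Leaving out an array gave medians from -0.59 to -0.24 and from -0.61 to -0.26. Medians were below 0 under both other scalings, at -0.32 and -0.55 for the respiratory genes and -0.18 and -0.40 for the ribosomal ones.

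Splicing factors were higher in part. Of 78 measured genes, 23 rose and 3 fell adjusted over the list alone, with a median of 0.11, and of 0.35 and 0.13 under median and 75th percentile scaling. Pnisr (1.89 ± 0.15) and Luc7l3 (1.37 ± 0.13) stood beside Hnrnph1 and Clk2, and the wild-type arrays differed by a median of 0.02. Camera gave p = 9.78e-05, and with an estimated correlation p = 0.0382 (0.115 adjusted over the 3 lists). Fry gave an adjusted p of 0.0268. Because genes that prompted the list are among its members, this is not independent evidence of its direction.

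Probes with large differences were mostly higher in the knockout (59.1% of those with an unadjusted p under 0.05 and 1.5-fold, with 51% and 50.8% without wild-type replicate 2 or 3 and 68.6% and 62.2% without knockout replicate 1 or 2). Scaling between arrays stays open: the ratio of higher to lower probes was 1.44 in the main setting, 4.57 under 75th percentile scaling and 75 under median scaling, so it follows the scaling, and the bound of 1.5 set for the test decides nothing because the main ratio already meets it. More unspliced or nuclear RNA, or genomic DNA, would need probes outside curated mRNAs to differ more towards the knockout. Over 1463 genes, probes of other accessions differed from those of curated mRNAs by a median of -0.0312 (95% interval -0.0501 to -0.0152), and over the 424 genes with bright probes by -0.00189 (-0.068 to 0.0673), neither in the direction it needs, but it stays open because an accession does not say whether a probe lies in an intron. Of the 3 splits of the 4 arrays only 1, the real one, gave as many as 4582 probes at an unadjusted p under 0.05, and the highest other gave 553, but 3 splits are too few for a share under 0.05.

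Beta-globin probes were lower in the knockout, with a median difference of -1.60. Less blood in the dissected knockout tumours may account for it: the alpha-globin probe differed by -1.07, more than 50% of the beta-globin difference and without overlap of the groups. A different beta-globin haplotype of the hosts would not by itself lower alpha-globin (95% interval -1.72 to -0.43) or Alas2 (-1.52, 95% interval -2.85 to -0.2). These 2 values go against haplotype as the whole account. They do not settle it, since neither gene passed the adjusted threshold (limma adjusted p = 0.157 and 0.253). A part of the beta-globin difference from haplotype stays open. Within arrays, the alpha-globin difference minus 50% of the beta-globin difference was -0.38, with a 95% interval of -0.91 to 0.14. The beta-globin difference used here was -1.38, from the median level of the 10 probes on each array. Fewer vessels also stay open, since the endothelial median of -0.14 was above 0 under median scaling. Its 95% interval over genes was -0.31 to 0.02, which holds the bound of -0.26 and leaves out the spread between mice. The absence of VAP-1 from the host and bleeding at dissection were not tested apart.

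Aoc2 was higher in the knockout by 1.03 ± 0.14, and by 0.40 at its second probe, both close to the floor in wild type. A change across the neighbourhood of the targeted locus stays open: 16 measured genes around Aoc2 and Aoc3 had a median absolute difference of 0.25, larger than in 76.1% of 12708 runs of neighbouring genes. That misses the 95% set for the test, but missing it is no value against the explanation. The 95% interval of 0.12 to 0.36 holds the median of the runs (0.19) and reaches their 95th percentile (0.36). The injected cells were also the same in both groups, so their share of the signal cannot show a change made by the targeted locus of the host. A shift shared by many probes stays open too: 2.03% of kept genes had a probe as much higher, but Aoc2 was singled out for its difference, so a small share was fixed by that choice. An effect of the targeted allele on Aoc2 itself may remain as a hypothesis, which was not tested.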
